A study of Mus musculus with 5 samples.

How the data were processed

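DamID libraries were made from mouse endothelial precursor cells derived from embryonic stem cells, with 1 library each for SOX7-Dam, FLI1-Dam, ERG-Dam, a Dam-only control for SOX7 and a Dam-only control for FLI1 and ERG. Per the labels' protocols, libraries were made from 50 ng of sheared DNA with 10 cycles of amplification and sequenced as single reads of 60 bp. The series design sets each factor against Dam alone, and the control of each factor was taken from the sample titles. The controls have no peak list of their own here, so no background value can be set beside a peak.

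The files of the 3 factor libraries list genes, each with an Ensembl identifier, symbol, biotype, a read count, a read density and the positions of the peaks assigned to it. Per the file headers the first value is a read count, and the deposited counts are whole numbers of reads in the listed peaks. Per the file headers the second value is a read count per kb, a coverage signal. Recomputing it as count times 1000 over the summed peak length returned the deposited signal, to rounding, in all 6530 SOX7, 10246 FLI1 and 1579 ERG genes. The authors' values are thus not scaled to library size and not divided by the control, and they are compared only within a list, as percentiles. Positions are on mm9, per the submitters' processing notes. The aligner, the peak caller and its threshold, the rule that assigns peaks to genes and the annotation release are not given in the sources used here, nor is whether a peak lies in an exon, an intron or between genes. Peak widths differ by multiples of 50 bp in all lists. A gene missing from a list had no assigned peak in it, which does not mean that it had no reads. Amplified reads carry no molecular identifiers, so Poisson and exact binomial (Clopper-Pearson) intervals cover counting error only.

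The lists carry signs of different annotation releases. The FLI1 list has 296 genes and the ERG list 44 genes of the biotype antisense, the SOX7 list 0. Of the 4511 genes common to SOX7 and FLI1, 191 (4.23%) have another biotype and 46 another symbol, while ERG and FLI1 differ in 0 of 1245. Genes were therefore matched by Ensembl identifier between lists. Genes near the edges of these annotations can be listed in one file and not in another for this reason.

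Overlap was counted between unique peaks, with a minimum of 1 bp. Random placements moved the peaks of one list together by a random distance within each chromosome, 10000 times in the main setting and 1000 times in the alternatives. Regions of all 3 factors are merged chains of overlapping peaks, so the 3 peaks need not share a base. The planned ranking used the authors' score or fold per peak. The files hold neither, so reads per kb took its place, with the read count as the other strength column. The density belongs to a gene with all its peaks, and a peak took that of the gene with the fewest peaks. It is the peak's own value for 42.6% of SOX7, 36.3% of FLI1 and 84.1% of ERG peaks and a mean over several peaks otherwise. The read count of a peak was taken from the same gene and is the sum over all peaks of that gene. Shared and other peaks were compared by the difference of their median percentiles, with 100000 random relabellings.

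The 11 gene lists, with 168 entries for 166 genes, the main tests and the alternatives were fixed before the data were examined, with exceptions. The random lists matched on peaks per gene and the tests of explanations in the closing part were chosen after. The plan also did not name the overlap by bins of density or the ratios of chromosome X to autosomes. Nor did it name shared genes set against independent lists, or housekeeping set against endothelial identity genes. Symbols were matched to the protein-coding genes of a RefSeq gene table of a later mouse assembly, used for names only, which recognised 96.5% of SOX7, 95.6% of FLI1 and 95.7% of ERG protein-coding genes, older symbols included. Each list was set against 10000 random lists of the same size from 21900 genes, with ties counted by mid-rank. The random lists are not matched on gene length, because gene models of mm9 were not used here, and long genes can collect more peaks. Named genes are the list members with a peak from all 3 factors, the 5 genes with the highest density per list and the 5 regions of all 3 factors with the best mean percentile. Others are said to be chosen after their values were seen.

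The overlap and random placement steps were tested on simulated lists. With 30% of SOX7 peaks placed on FLI1 peaks, 31.8% were found to overlap, and with 0% placed the fold over random was 0.952. The same test gave 30.5% and a fold of 1.13 for ERG with SOX7, and 31.6% and a fold of 0.920 for ERG with FLI1. Alternatives changed the overlap rule, the part of each list used (of its peaks for overlaps, of its matched protein-coding genes for gene lists), the random placements and the strength column. Searches for SOX and ETS motifs and windows around gene starts were left out because no sequence or gene models of mm9 were used here. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.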

Results

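DamID was used to map where the transcription factors SOX7, FLI1 and ERG contact the genome of mouse endothelial precursor cells. In this assay a factor is fused to the bacterial methylase Dam, which marks adenines in GATC sites near the places the factor visits, and the marked DNA is sequenced. Dam alone, with no factor attached, marks accessible DNA and serves as the control. SOX7 is a SOX family factor of the blood and vessel lineages, and FLI1 and ERG are closely related ETS family factors. The cells were derived from embryonic stem cells: FLK1-positive cells were isolated at day 3 of embryoid body culture, kept for 1 day in blast culture and sorted as cKIT-positive and TIE2-positive. There were 5 libraries, 1 each for SOX7-Dam, FLI1-Dam and ERG-Dam, 1 Dam-only control for SOX7 and 1 Dam-only control shared by FLI1 and ERG. The labels give each factor its own cell line, iSox7::Dam, IFli1::Dam and iErg::Dam. Differences between factors can therefore not be told apart from differences between lines. With 1 library per group no difference between factors has a replicate check, and no p-value is given. Intervals below cover counting error only.

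The first question was how much of the genome each factor marked. FLI1-Dam had the longest list, with 16834 peaks assigned to 10246 genes, followed by SOX7-Dam with 10029 peaks at 6530 genes. ERG-Dam had 1588 peaks at 1579 genes. Protein-coding genes made up 8122, 5243 and 1319 of the listed genes of FLI1, SOX7 and ERG. The peaks had a median width of 1650 bp for FLI1, 1450 bp for SOX7 and 950 bp for ERG, and covered 32.0, 16.9 and 1.82 Mb. Most listed genes carried 1 peak, namely 64.0% in the FLI1 list, 68.9% in the SOX7 list and 92.0% in the ERG list. The listed peaks held 2665309 reads for FLI1, 974550 for SOX7 and 135623 for ERG, counting each distinct set of peaks once. These sums follow how much was called, and library depth is not given in the sources used here. The median gene had 169 reads (95% Poisson interval 144 to 196) for FLI1, 95 reads (76.9 to 116) for SOX7 and 36 reads (25.2 to 49.8) for ERG. List length and reads per kb are therefore described within each list and are not read as differences in binding.

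The 5 genes with the highest read density were mostly different between lists. In the SOX7 list Egfl7, which encodes a protein secreted by endothelial cells, ranked second with 3041 reads and 608 reads per kb (587 to 630), 12.5 times the list median, in 1 peak on chromosome 2 from 26426499 to 26431499 (mm9). Abt1 ranked first with 656 reads per kb on chromosome 13 from 23503753 to 23504853. The pseudogene Gm12849 followed with 595 reads per kb (chromosome 4, 115381826 to 115383226), then Creb3l4 with 416 and the histone gene Hist1h2bh with 405. In the FLI1 list the highest densities were at the predicted genes Gm10800 with 7592 reads per kb (chromosome 2, 98504998 to 98507498), Gm10222 with 6435 (chromosome 1, 24618357 to 24619657) and Gm10801 with 4409 (chromosome 2, 98502348 to 98504248). Abt1 came next with 1064 reads per kb, then Gm4285 with 675. In the ERG list Gm10222 had 15587 reads per kb (chromosome 1, 24618336 to 24620536) and 25.3% of all listed reads. The pseudogene AY036118 followed with 5782 reads per kb over 2 peaks between 39980004 and 39985104 on chromosome 17. A peak on chromosome 2 from 22442788 to 22444588, assigned to Myo3a, Gm13340 and Gm13341, had 520. Gm10800, Gm10222 and Gm10801 stood at 110, 93.5 and 64.0 times the FLI1 median. Gm10222 and AY036118 stood at 493 and 183 times the ERG median. Whether such extreme densities reflect binding of the factor was not tested, and no alternative below was run without these peaks.

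The central comparison asked whether SOX7 and the ETS factors marked the same regulatory genes. Among 28 genes of endothelial identity, 23 were listed for FLI1, 17 for SOX7 and 5 for ERG. These are shares of 82.1% (exact binomial interval 63.1 to 93.9), 60.7% (40.6 to 78.5) and 17.9% (6.06 to 36.9), against 35.5%, 23.1% and 5.74% in random lists of protein-coding genes. The fold over random lists was 2.31, 2.63 and 3.11, at percentiles 100, 100 and 98.8 of 10000 random lists. Among the 1260 densest protein-coding genes of the SOX7 list, the size of the ERG list, 3 of the 28 genes were left, a fold of 1.86 at percentile 85.3. Against random lists matched on the number of peaks per gene in another factor's list, a setting chosen after seeing the data and called matched lists from here on, the folds were 1.43 for FLI1 (percentile 99.9), 1.38 for SOX7 (97.7) and 1.38 for ERG (79.0). SOX7 and FLI1 shared 14 of the 28 genes, about as many as independent picks of 17 and 23 among 28 would share. Eng, Esam, Icam2 and Egfl7 were listed for all 3 factors. Eng, a coreceptor for TGF-beta family ligands, stood at percentile 81.5 of the ERG list, 77.7 of the FLI1 list and 64.6 of the SOX7 list. The adhesion molecule gene Esam stood at percentile 93.3 of the FLI1 list with 150.3 reads per kb, at 75.5 of the ERG list with 55.9 and at 33.5 of the SOX7 list with 39.7. Icam2, another adhesion molecule gene, stood at percentiles 90.7, 61.3 and 54.0 of the FLI1, ERG and SOX7 lists. Cdh5 (VE-cadherin), Kdr (FLK1) and Tek (TIE2), chosen after their values were seen, were listed for SOX7 and FLI1 and not for ERG. Kdr carried 4 SOX7 peaks with 995 reads and 3 FLI1 peaks with 810 reads. FLK1 and TIE2 were also the markers used to sort the cells.

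**Figure D1:**
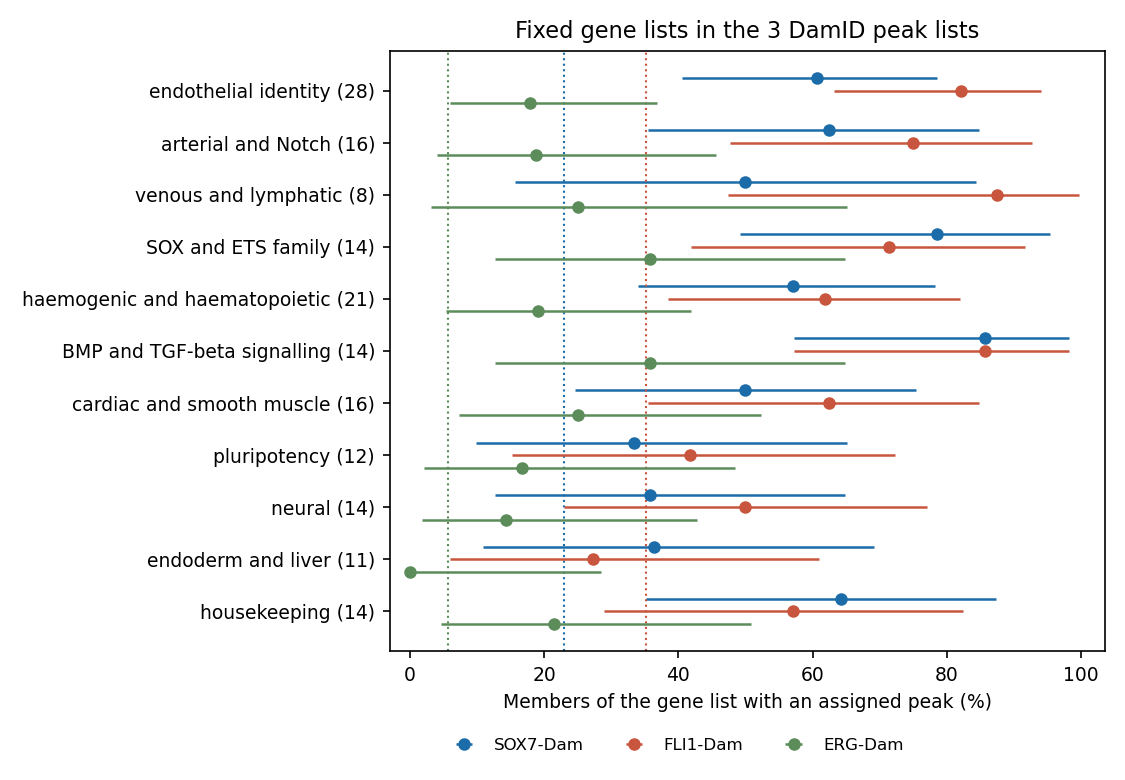
Share of the members of 11 gene lists with an assigned peak (horizontal axis, percent) for SOX7-Dam, FLI1-Dam and ERG-Dam; points are the shares, bars the exact 95% binomial intervals, dotted lines the mean share in random lists, and the number of members stands in parentheses. Endothelial identity genes were at 82.1% for FLI1, 60.7% for SOX7 and 17.9% for ERG, and housekeeping genes at 57.1%, 64.3% and 21.4%.

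Genes of the SOX and ETS families were themselves among the listed genes. Of 14 members, 11 were listed for SOX7 (78.6%, 49.2 to 95.3), 10 for FLI1 (71.4%, 41.9 to 91.6) and 5 for ERG (35.7%, 12.8 to 64.9), folds of 3.42, 2.02 and 6.19 over random lists. Against matched lists the folds were 1.63 (percentile 99.7), 1.05 (61.4) and 2.37 (97.9). Sox7, Erg, Ets1 and Etv6 were listed for all 3 factors. Sox7 had 352 reads per kb (331 to 374) in the FLI1 list, at percentile 99.6, 131 (117 to 146) in the SOX7 list, at percentile 96.3, and 44.6 (36.1 to 54.5) in the ERG list, at percentile 66.2. Peaks of all 3 factors met at 64576473 to 64578607 on chromosome 14. Erg carried 5 FLI1 peaks, 2 SOX7 peaks and 1 ERG peak, and the ERG peak at 95660642 to 95662792 on chromosome 16 lay inside the FLI1 peak at 95657974 to 95663824 and met the SOX7 peak at 95659048 to 95662748. Ets1 had 8 FLI1, 7 SOX7 and 2 ERG peaks, with a region of all 3 at 32452201 to 32455704 on chromosome 9. Etv6 had 14 SOX7, 9 FLI1 and 1 ERG peaks, and no region held all 3. Its ERG peak had 18 reads at 10.3 reads per kb, percentile 0.7 of the ERG list. Fli1, chosen after its values were seen, had 9 SOX7 peaks with 1520 reads and 7 FLI1 peaks with 1416 reads, and was not in the ERG list.

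Arterial and Notch pathway genes were listed in 12 of 16 cases for FLI1 (75.0%, 47.6 to 92.7), 10 for SOX7 (62.5%, 35.4 to 84.8) and 3 for ERG (18.8%, 4.05 to 45.6), at percentiles 99.9, 99.9 and 96.6 of random lists. Against matched lists these percentiles were 97.4, 96.9 and 78.5, all below the 97.5 that bounds the central 95% of such lists. Nrp1, which encodes a VEGF coreceptor, was listed for all 3, at percentile 94.3 of the SOX7 list with 115 reads per kb, 62.2 of the FLI1 list and 47.9 of the ERG list, and no region held peaks of all 3 factors there. Among 8 venous and lymphatic genes 7 were listed for FLI1, 4 for SOX7 and 2 for ERG, at percentiles 99.8, 94.5 and 96.3 of random lists and 99.2, 62.8 and 83.3 of matched lists. Among the 1260 densest genes 2 were left for FLI1 (percentile 95.8), and the denser 50% of ERG genes held 0 of the 8. Nr2f2, a regulator of venous identity, was listed for all 3. It stood at percentile 64.3 of the FLI1 list, 81.0 of the SOX7 list and 5.8 of the ERG list, there with 11 reads.

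Haemogenic and haematopoietic genes were listed in 13 of 21 cases for FLI1 (61.9%, 38.4 to 81.9), 12 for SOX7 (57.1%, 34.0 to 78.2) and 4 for ERG (19.0%, 5.45 to 41.9), folds of 1.76, 2.47 and 3.33 over random lists. Against matched lists the folds were 1.09 (percentile 71.7), 1.56 (98.6) and 1.89 (90.5). Runx1, needed for blood cells to form from endothelium, carried 10 FLI1 peaks with 2669 reads, 4 SOX7 peaks with 457 reads and 2 ERG peaks with 152 reads, and 2 regions held all 3 factors, at 92692824 to 92700024 and 92715498 to 92716542 on chromosome 16. Spi1, given under its older symbol Sfpi1 in the files, stood at percentile 56.8 of the ERG list, 24.0 of the FLI1 list and 22.7 of the SOX7 list, with a region of all 3 at 90917138 to 90920498 on chromosome 2. Ikzf1 was also listed for all 3, with 5 SOX7 peaks, 1 FLI1 peak and 1 ERG peak that met in no region of all 3.

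The remaining gene lists gave a mixed result. BMP and TGF-beta signalling genes were listed in 12 of 14 cases for both SOX7 and FLI1 (85.7%, 57.2 to 98.2) and 5 for ERG, folds of 3.73, 2.44 and 6.21 over random lists and 1.77 (percentile 99.9), 1.31 (96.0) and 2.68 (98.5) over matched lists. Smad7, an inhibitor of this pathway, stood at percentile 98.5 of the SOX7 list with 171 reads per kb (150.3 to 193), 97.8 of the ERG list with 164 (142 to 189) and 93.5 of the FLI1 list with 152 (140.0 to 164). Bmp2, Bmpr2 and Tgfb1 were also listed for all 3. In the denser 50% of genes, 2 of the 14 were left for ERG, at percentile 96.7 of random lists. There SOX7 kept 5 (percentile 99.1) and FLI1 kept 8 (99.9). Cardiac and smooth muscle genes were listed in 10 of 16 cases for FLI1, 8 for SOX7 and 4 for ERG, at percentiles 98.4, 98.9 and 99.4 of random lists and 87.7, 74.3 and 91.5 of matched lists. The cardiac regulators Gata4, Tbx5 and Nkx2-5 were listed for all 3, and Nkx2-5 had 250 ERG reads at 122 reads per kb, percentile 94.8. Housekeeping genes were listed in 9 of 14 cases for SOX7 (64.3%, 35.1 to 87.2), 8 for FLI1 (57.1%, 28.9 to 82.3) and 3 for ERG (21.4%, 4.66 to 50.8), with Actb and Tbp listed for all 3. The folds over random lists were 2.77 for SOX7 (percentile 99.9), 1.64 for FLI1 (95.2) and 3.73 for ERG (97.4), and against matched lists 2.18 (99.9), 1.10 (66.0) and 2.92 (95.9). The share of housekeeping genes for SOX7 was thus not below that of endothelial identity genes, and the intervals overlapped for each factor. Within the denser 50% of the protein-coding genes of each list, 2 of 14 housekeeping genes and 13 of 28 endothelial identity genes were listed for SOX7, 6 and 17 for FLI1, and 3 and 5 for ERG. For ERG these counts were the same as in the full list, with the housekeeping share, 21.4%, above the endothelial identity share of 17.9%.

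Pluripotency genes were listed in 5 of 12 cases for FLI1, 4 for SOX7 and 2 for ERG, with Sall4 listed for all 3. Neural genes were listed in 7 of 14 cases for FLI1, 5 for SOX7 and 2 for ERG, with Pax6 and Nes listed for all 3. Endoderm and liver genes were listed in 3 of 11 cases for FLI1, 4 for SOX7 and 0 for ERG. The counts of these last lists lay between percentiles 26.2 and 91.1 of random lists. Of 25 list members listed for all 3 factors, 17 had at least 1 region holding peaks of all 3, and at 16 the peaks of all 3 were assigned to that gene.

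**Figure D2:**
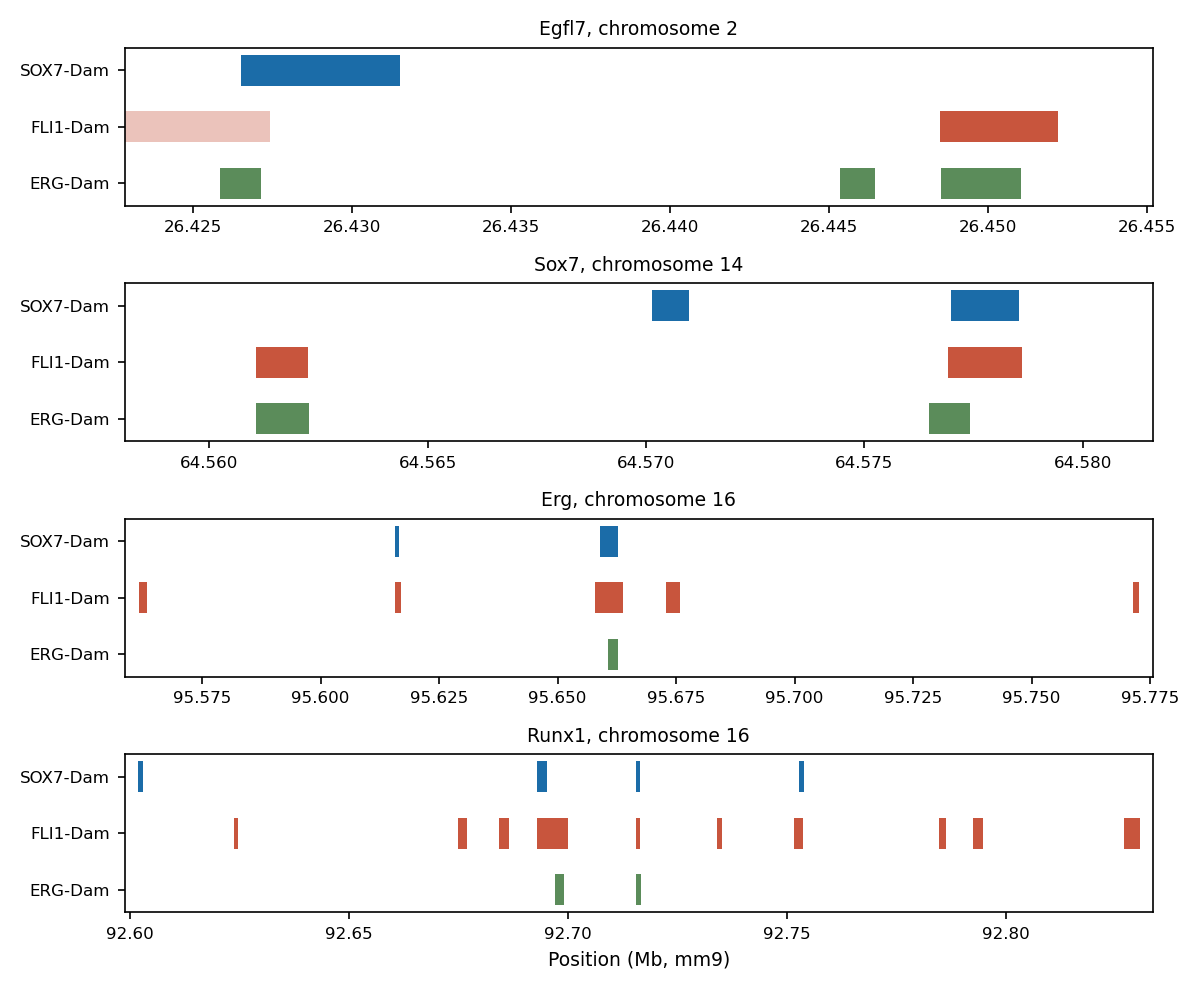
Peaks of the SOX7-Dam, FLI1-Dam and ERG-Dam lists at Egfl7, Sox7, Erg and Runx1 (horizontal axes, position in Mb, mm9; each row is 1 list, each box 1 peak to scale, and a pale box is a peak the files assign to another gene). Erg carried 5 FLI1 peaks, 2 SOX7 peaks and 1 ERG peak, and Runx1 carried 10, 4 and 2.

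The next comparison was between peak positions. Of the SOX7 peaks 35.2% (34.3 to 36.1) overlapped a FLI1 peak by at least 1 bp, 3529 of 10029, against 2.38% after random placement along the same chromosome, a fold of 14.8. Of the ERG peaks 49.3% (46.8 to 51.8) overlapped a FLI1 peak, 783 of 1588, a fold of 24.0, and 32.4% (30.1 to 34.8) overlapped a SOX7 peak, 515 of 1588, a fold of 28.6. The largest of 10000 random placements gave 440 overlaps for SOX7 with FLI1, 89 for ERG with FLI1 and 49 for ERG with SOX7. Each peak was also moved by 20 to 500 kb, which keeps its wider region but not its place relative to genes. The folds were then 9.10, 14.2 and 17.2. Neither kind of placement was limited to DNA with GATC sites or to DNA where reads can be mapped. How much this raises the folds was not tested. FLI1 and ERG were set against the same Dam-only library, so part of their overlap may come from that shared control, and this cannot be separated with 1 control library.

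Merging all peaks gave 23972 regions, of which 411 (1.71%) held peaks of all 3 factors. Random placements gave a mean of 0.740 and a maximum of 5. These placements also break the overlap of each pair. The contrast therefore does not show a preference for all 3 factors beyond that of the pairs. SOX7 and FLI1 without ERG shared 3078 regions, FLI1 and ERG without SOX7 374, and SOX7 and ERG without FLI1 123. FLI1 alone held 12935 regions, SOX7 alone 6377 and ERG alone 674. The region with the best mean rank was at Fam69a (chromosome 5, 108416499 to 108417871), with a mean percentile of 99.5 over the 3 lists. The next were at Alyref2 (chromosome 1, 173432257 to 173435958, 99.0), Cbx5 and Hnrnpa1 (chromosome 15, 103068612 to 103073229, 98.9), Ceacam19 (chromosome 7, 20460648 to 20462545, 98.5) and Rps13-ps1 (chromosome 8, 89585491 to 89586841, 98.4). None of these 5 regions was assigned to a member of the gene lists. The regions of all 3 at vessel genes included Esam (chromosome 9, 37334901 to 37339353), Eng (chromosome 2, 32508399 to 32511498) and Icam2 (chromosome 11, 106243634 to 106245948). At Egfl7 the region from 26422748 to 26431499 on chromosome 2 held the SOX7 peak and 1 ERG peak of this gene, while its FLI1 peak is assigned to another gene in the files. The FLI1 peak assigned to Egfl7, at 26448498 to 26452198, overlapped an ERG peak and no SOX7 peak.

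Shared peaks were also the denser ones in each list. ERG peaks that overlapped SOX7 had a median percentile of 69.4 in the ERG list, against 40.1 for those that did not, a difference of 29.3 points. FLI1 peaks shared with ERG stood 29.0 points higher than the rest, and those shared with SOX7 22.5 points. SOX7 peaks shared with ERG stood 17.9 points higher and those shared with FLI1 13.2 points, and ERG peaks shared with FLI1 22.4 points. Each difference was beyond the largest of 100000 random relabellings of the same peaks, which were between 4.38 and 11.3 points. Peaks are not replicates, so this describes these lists. With the read count in place of the density, the difference for SOX7 peaks shared with ERG was 7.27 points, below the largest relabelled value of 8.70. A peak took the summed read count of its gene, so this ranking also follows the number of peaks per gene. Among the densest 10% of ERG peaks 71.1% (63.4 to 78.0) overlapped FLI1, and among the least dense 10% of them 25.0% (18.5 to 32.5).

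**Figure D3:**
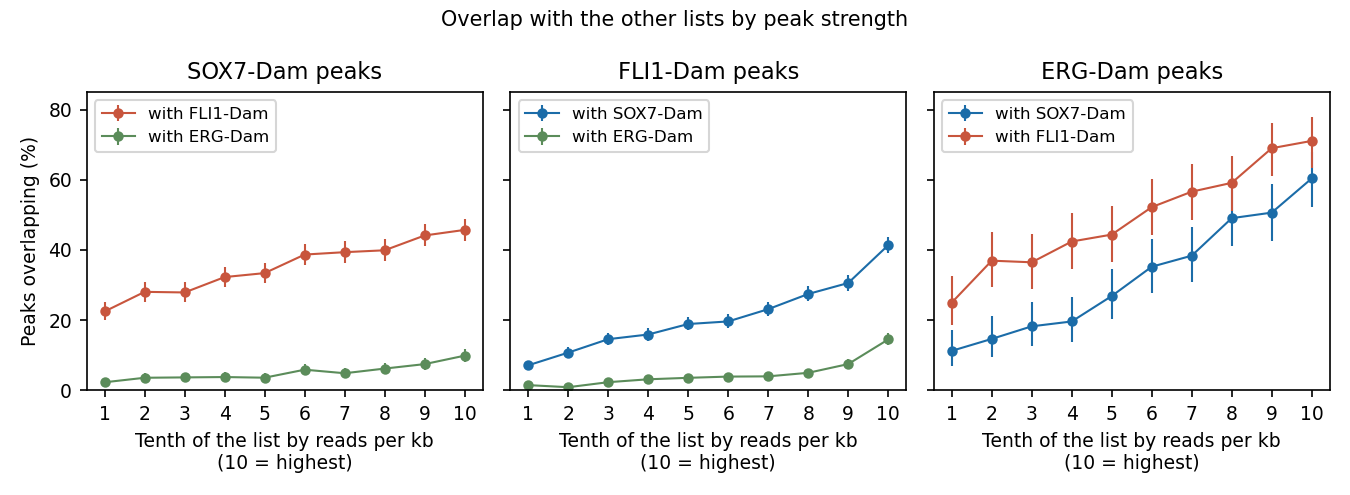
Share of peaks overlapping another list (vertical axis, percent) by reads per kb in 10 bins of equal size (horizontal axis, 10 is the highest), for SOX7-Dam, FLI1-Dam and ERG-Dam peaks; bars are exact 95% binomial intervals. ERG peaks overlapped FLI1 in 25.0% of the lowest and 71.1% of the highest bin.

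At the level of genes, SOX7 and FLI1 had 4511 genes in common, 69.1% (67.9 to 70.2) of the SOX7 genes. ERG shared 1245 genes with FLI1, 78.8% (76.7 to 80.8) of its list, and 968 with SOX7, 61.3% (58.9 to 63.7). All 3 lists held 876 genes, 754 of them protein-coding. A shared gene did not always mean a shared peak: the peaks overlapped at 64.2% of the genes common to SOX7 and FLI1, 65.1% of those of ERG and FLI1 and 55.3% of those of ERG and SOX7. Among 21900 protein-coding genes, independent lists of these sizes would share 1780 genes for SOX7 and FLI1, 445 for ERG and FLI1 and 290.2 for ERG and SOX7. The observed numbers were 3636, 1031 and 799, folds of 2.04, 2.32 and 2.75. The expectation leaves out the control shared by FLI1 and ERG. It also takes each of the 21900 genes as equally likely to be listed, although long genes can collect more peaks. How much this adds to the 3 folds was not tested.

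Genes on chromosome X had fewer reads per kb in their peaks than genes on autosomes in each list. The median was 28.5 for genes on X and 50.4 for genes on autosomes in the SOX7 list, a ratio of 0.566 (95% bootstrap interval over genes 0.540 to 0.603). In the FLI1 list the medians were 42.1 and 70.4, a ratio of 0.598 (0.564 to 0.630), and in the ERG list 22.5 and 32.5, a ratio of 0.690 (0.600 to 0.786). The lowest median of an autosome was 45.7 in the SOX7 list and 65.4 in the FLI1 list. In the ERG list chromosome 19 had a median of 22.8, about as low as X.

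**Figure D4:**
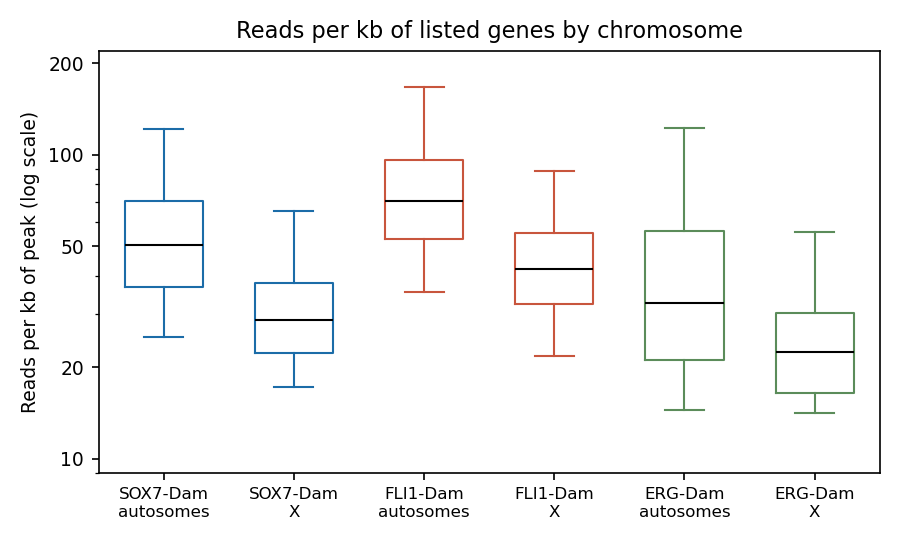
Reads per kb of peak (vertical log axis) for listed genes on autosomes and on chromosome X in the SOX7-Dam, FLI1-Dam and ERG-Dam lists; the line is the median, the box the quartiles and the whiskers reach percentiles 5 and 95. The medians on X were 28.5, 42.1 and 22.5, against 50.4, 70.4 and 32.5 on autosomes.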

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

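The fold of peak overlap over random placement stayed far above 1 under each alternative tried, while its size followed the setting; values are for SOX7 with FLI1, ERG with SOX7 and ERG with FLI1. Requiring 50% of the shorter peak gave 21.2, 41.9 and 35.1, and midpoints within 500 bp gave 28.0, 46.5 and 40.9. A gap of up to 1000 bp gave 10.2, 17.6 and 15.2, and local shifts gave 9.10, 17.2 and 14.2. The denser 50% of each list gave 26.4, 58.3 and 47.4. The 1588 densest peaks of each list gave 77.3, 50.3 and 75.0, where the overlapping share was 18.8%, 9.13% and 14.9%, so the order of the pairs changed. By construction, stricter rules and shorter lists lower the random mean. Regions of all 3 factors numbered 411, and there were 145 with midpoints within 500 bp (counted as ERG peaks), 217 in the denser 50% and 74 among the densest 1588. The denser 50% held 5014 SOX7, 8417 FLI1 and 794 ERG peaks by construction.

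With the read count in place of the density, shared peaks stood 7.27 points higher for SOX7 with ERG and 19.0 for FLI1 with SOX7. They stood 16.9 points higher for FLI1 with ERG and 28.0 for ERG with FLI1. The read count sums all peaks of a gene, so it also ranks peaks by how many their gene has. How much this moved the differences was not tested. For genes, the denser 50% and the 1260 densest (the size of the ERG list) were taken from the protein-coding genes of each list, not from its peaks. The fold of endothelial identity genes was 4.08 for SOX7 and 3.44 for FLI1 in the denser 50% and 4.31 for FLI1 among the 1260 densest, but 1.86 (percentile 85.3, 3 genes) for SOX7 among the 1260 densest. It was 1.38 for SOX7 and 1.43 for FLI1 against random lists matched on peaks per gene, the only setting chosen after seeing the data; this matching takes genes that another factor also lists. Genes listed by both had folds of 2.92 (SOX7 with FLI1), 4.05 (ERG with SOX7) and 3.55 (ERG with FLI1) in the denser 50% and 4.54, 3.37 and 3.81 among the 1260 densest. Housekeeping genes went from a fold of 2.77 in the full list to 1.24 in the denser 50% for SOX7, but from 1.64 to 2.43 for FLI1 and from 3.73 to 7.63 for ERG, where endothelial identity genes had 6.24. Of the 11 gene lists, 7 for SOX7, 7 for FLI1 and 5 for ERG lay above percentile 97.5 of random lists; these numbers were 7, 6 and 4 in the denser 50%, 5, 4 and 5 among the 1260 densest and 5, 2 and 2 against matched lists. No value changed direction in 64 alternatives of the results other than single gene lists, endothelial identity included, of which 39 moved beyond their limits. Counts of peaks and of regions of all 3 factors have no direction to change. Local shifts keep the 411 regions, and the 1260 densest ERG genes are all matched protein-coding genes of ERG. Both therefore repeat the main counts by construction. For the other gene lists 65 of 90 alternatives, matched lists included, stayed within the interval of the main fold and 25 moved. Staying within it does not mean that a count stayed above percentile 97.5, and some folds near 1 crossed it, such as pluripotency genes for FLI1 from 1.18 to 0.476 in the denser 50%.

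Windows of 10 and 100 kb around genes and motif searches were not run, for want of mm9 sequence and gene models. No paired analysis was possible because each factor has 1 library. Shares of lists with 8 to 28 genes have wide intervals, and the median ERG gene rests on 36 reads.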

Other observations

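All tests of explanations in this part were chosen after the result was seen. Magi1, Fgfr2, Arfip1, Gm20388 and Etv2 were also chosen after their values were seen. The genes with the most peaks were mostly outside the gene lists. Magi1, which encodes a scaffold protein of cell junctions, carried 21 SOX7 and 14 FLI1 peaks and 0 ERG peaks. Fgfr2, a fibroblast growth factor receptor gene, carried 40 FLI1, 15 SOX7 and 3 ERG peaks, and Arfip1 carried 21, 19 and 1. The locus Gm20388, under another symbol in the SOX7 list, carried 60 FLI1, 15 SOX7 and 13 ERG peaks. Etv2, an ETS factor gene at the start of the endothelial and blood programme, had 733 ERG reads in 2 peaks at 110 reads per kb (102 to 118), percentile 93.0, and 112 SOX7 reads in 1 peak. It was not in the FLI1 gene list, although a FLI1 peak assigned to another gene overlapped its SOX7 peak at 31421648 to 31424098 on chromosome 7. Gm10222 and AY036118, with 34307 and 15623 ERG reads, were absent from the SOX7 list.

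Peaks of the 3 lists overlapped far more than random placement. A shared Dam-only control is excluded as the whole cause, because SOX7 and FLI1 were set against different controls and their fold was 14.8. The smallest fold over local shifts was 9.10, which argues against clustering of peaks in wide gene-rich regions as the whole cause. Shifts of 20 to 500 kb do not keep the place of a peak relative to genes. Clustering on a scale finer than 20 kb therefore stays open. Open chromatin shared by active genes cannot be told apart from a shared programme: 50.0% (23.0 to 77.0) of housekeeping genes and 50.0% (30.6 to 69.4) of endothelial identity genes were listed by both SOX7 and FLI1. Within the denser 50% of genes these shares were 7.14% (0.181 to 33.9) and 32.1% (15.9 to 52.4), and 14 housekeeping genes are too few to decide. That SOX7 and ETS factors visit the same elements stays open, as does a bias towards accessible DNA beyond that of Dam alone.

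The ERG list was much shorter than the others. If it were a shallower sample of the FLI1 profile without false calls, nearly all of its peaks would lie on FLI1 peaks, and 49.3% (46.8 to 51.8) did. No other FLI1 library shows what share a shallow sample with weak or false calls would give. The share therefore cannot decide whether depth was the cause. The share rose with density, as it did in the longer lists: from 7.13% to 41.4% for FLI1 peaks on SOX7 peaks and from 22.5% to 45.7% for SOX7 peaks on FLI1 peaks, between the least dense and the densest 10%. False calls in the ERG list and sites that ERG visits and FLI1 does not were not tested and stay open.

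Reads per kb were lower on chromosome X. Fewer copies of X than of autosomes per cell may lower the reads of factor and control alike in the SOX7 and FLI1 lists, where the higher ratio of medians was 0.598 and percentile 5 was lower too. Weaker binding on X alone, under a common threshold, would leave percentile 5 of the density equal. The higher of its ratios between X and autosomes was 0.678 (0.616 to 0.723, SOX7), which argues against weaker binding as the only cause. Fewer copies would lower percentile 5 whether or not binding on X was also weaker, and the threshold is not known. Weaker binding beside fewer copies therefore stays open. The ratio of medians was below that of percentile 5 for SOX7 (0.566 and 0.678), but not for FLI1 (0.598 and 0.593). In the ERG list the ratio of percentile 5 was 0.979 (0.922 to 1.04), and this cannot be told apart from a floor set by a minimum of reads, since percentile 5 of the read counts was 13 and the lowest count 10. The sex of the cell lines was not given in the labels used, and no biological explanation by group was tested.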
